A study of Mus musculus with 3 samples.

How the data were processed

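Formalin-fixed, paraffin-embedded sections of 3 mammary tumours titled MMTV-PyMT WT, 1 section per tumour, were imaged on the Vizgen MERSCOPE platform with a custom gene panel, per the labels. What WT refers to is not given in the sources used here. MMTV-PyMT mice carry the polyoma middle T oncogene under a mammary promoter and develop mammary carcinomas. MERSCOPE reads single transcripts in place by multiplexed error-robust fluorescence in situ hybridization and assigns them to segmented cells. The 3 tumours formed 1 group, and the tumour was the unit of replication throughout (n = 3). The design text states a panel of 265 genes. The tables used here hold 258 gene columns and 27 blank control codes, which match no gene and measure false decoding.

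The deposited tables give raw counts of decoded transcripts per cell and gene, per the file headers, with no normalization. Deposited cell tables give the volume and the centre of each cell. Their headers state no unit, and µm and µm3 were assumed from the extents of the cells. In every cell of all 3 sections the sum of gene and blank counts equalled the deposited transcript total. Cells were listed down to 0 transcripts. Segmentation and decoding software are not given in the sources used here, and the submitters' processing notes name Scanpy 1.9.3 without its role. Images and positions of single transcripts were not used here.

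Cells were kept with at least 20 panel transcripts and a volume from 50 µm3 to 3 times the section's median. Volume limits removed 6401, 6530 and 4653 cells of tumours 1, 2 and 3, and the count minimum removed 36974, 53438 and 107874. No doublet caller was run, because mixing in segmented images comes from neighbouring cells. It was instead addressed by leaving out the neighbour's markers, by counting genes higher in the neighbour class apart, and by repeating tests on cells without any marker transcript. A gene was called above background where its total exceeded that of the highest blank in all 3 sections. This held for 132 genes, while 102 genes were not above it in any section.

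For clustering, 20000 cells per section (seed 1) were scaled to 100 counts, log transformed and clipped at 10 SD, then reduced to 30 principal components. A graph of 15 neighbours was clustered by the Leiden method at resolution 1 with 5 iterations. All other cells took the nearest cluster centroid, which returned 77.7% of the sampled cells to their own cluster. A cluster took the name of a fixed list where at least 3 of its markers, above the highest blank, were 2-fold higher than in other cells and no list had more among the top 10 genes. Since most cells are epithelial, an epithelial-like cluster needed at least 3 epithelial markers 2-fold above the mean of the other named clusters, and was refused where another list had at least 2 such markers among the top 10 genes and more than the epithelial list. The lists held 10 epithelial markers on the panel, 7 fibroblast, 5 pericyte or smooth muscle, 3 endothelial, 9 macrophage, 4 dendritic, 3 neutrophil, 13 T or NK cell and 2 adipocyte markers. No marker on the panel came from the lists for B or plasma cells, mast cells, neural, skeletal muscle or erythroid cells. These naming rules for clusters were completed after the clusters were seen. One cluster with macrophage and dendritic markers was called myeloid-like, one led by the endothelial genes Pecam1 and Cdh5 was used as the endothelial neighbour although only 2 of its markers were detected, and one cluster stayed unnamed. Of 14 epithelial-like clusters, 5 held more markers of another class than of their own among their top 10 genes (38.3% of epithelial-like cells). Of these, the cluster led by Top2a and Mki67 held 1 such marker, Arg1. Another 2, with Krt5, Krt14 and Krt15 among their top 10 genes, were taken as the basal keratin clusters. A cluster led by Krt17, Fosb and Fn1 was not among them.

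Tissue was outlined on a grid of 25 µm. The margin was set at up to 150 µm from the outer edge and the interior at 500 µm or more. The outline met the imaging limit along 1575 µm in tumour 2 and 3025 µm in tumour 3, and was continued outward there, so that the end of the image was not taken as an edge. Cells outside the outlined tissue took no class, which left 618896, 452773 and 672539 cells. An epithelial-like cell was near a class with a cell centre of it within 25 µm and far with none within 75 µm. Counts of epithelial-like cells were summed per tumour and arm, giving 6 sums per comparison, each from at least 100 cells.

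Sums were tested in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with filterByExpr, TMM normalization, the tumour as a block and the quasi-likelihood F-test, which is two-sided. Benjamini-Hochberg adjustment ran over the genes tested, with a threshold of 0.05. Fold changes are log2 values with their standard error (SE). Levels are counts per 1000 panel transcripts, given as mean ± SD over the 3 tumours. Cell numbers per class were tested in the same way without TMM. Fixed gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, where a list had at least 3 measured members. The hypoxia list had 0 genes on the panel, so its tests and 2 planned correlations were not computable.

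Moran's I was computed per tumour over square bins of 100 µm with at least 10 epithelial-like cells. It used queen neighbours and Pearson residuals (negative binomial dispersion parameter 100). A gene counted as spatially structured where its I exceeded that of every blank and of every gene in 100 shuffles of the bins, in each tumour. Program scores per bin were correlated within each tumour. Adjacency of classes was the log2 ratio of observed to expected cell pairs within 25 µm. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

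The comparisons, gene lists, thresholds and the rule for genes named in the text were fixed before the data were examined. Per comparison the rule took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with 1 sign in all 3 tumours. It added up to 2 further members with the smallest p from each list of at least 3 measured members. For Moran's I it took the top 15 genes and the highest of each list, and for levels the 10 most abundant and the 5 most variable genes at 1 or more per 1000. Some genes the rule takes are not reported here. Outside the rule, Gata3 at the margin, Top2a, Mmp2 and Rgs5 near the Pecam1- and Cdh5-led cluster, and Mki67, Foxc2 and Isg15 near fibroblast-like cells were named after their values were seen. Alternatives covered normalization by library size or by summed cell volume, DESeq2 1.42.0, no gene filter, no block, other cell filters, other distances and bins, resolution 2, cells without marker transcripts, and leaving out each tumour. Leaving out basal keratin clusters, clusters with more markers of another class, or genes not above background was added after seeing the data.

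The edgeR test was tested on simulated data with 258 genes, 20 of them changed per fold size, in 20 simulations. It recovered 48% of genes changed 1.5-fold at the margin, 69.5% for the Pecam1- and Cdh5-led neighbour, 49% for the fibroblast-like one and 58% for the myeloid-like one. At 2-fold it recovered 82.8%, 96.8%, 91.5% and 93.3%. False calls per simulation were 1.95, 1.45, 1.95 and 2. For Moran's I on the 4735 bins of tumour 1, 20 of 20 genes with a 2-fold gradient were counted, and 12 of 20 at 1.2-fold, when gradients ran in both directions. All gradients running in one direction left 20 of 20 and 6 of 20 counted, together with 68 of 218 unchanged genes, so a shared gradient of many genes carries unchanged ones with it.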

Results

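Transcripts of 258 panel genes were counted in single cells of 3 mammary tumours labelled MMTV-PyMT WT, a single group without a control. Tumour 1 gave 71492483 panel transcripts in 663145 cells, tumour 2 gave 60759690 in 513963, and tumour 3 gave 78051090 in 786165. After filtering, 619770, 453995 and 673638 cells remained, with medians of 98, 106 and 94 transcripts per cell. Blank codes took 0.503%, 0.481% and 0.496% of all decoded transcripts. The tissue covered 48.9, 71.2 and 84.6 mm2. The series design names transcriptional heterogeneity in space as its subject, and the comparisons take position, neighbouring cells and spatial pattern in turn.

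Epithelial-like cells made up 87.1% ± 3.7 of the kept cells inside the outlined tissue (SD, n = 3; 618896, 452773 and 672539 cells). Fibroblast-like cells made up 6.35% ± 1.19, in a larger cluster led by the collagen gene Col1a1 and a smaller one led by Clec3b and Cd163. The smaller cluster held Cd163 and Folr2, both on the macrophage list, among its top 10 genes, so it may mix fibroblasts and macrophages. At clustering resolution 2 a cluster led by Cd163, Ccl8 and Folr2 was named myeloid-like. A myeloid-like cluster led by Adgre1, Cx3cr1 and the class II gene H2-Aa took 2.25% ± 1.32. The cluster led by the endothelial junction genes Pecam1 and Cdh5 took 1.79% ± 0.49, pericyte-like cells with Pdgfrb and Rgs5 took 0.887% ± 0.152, and an unnamed cluster took 1.62% ± 1.05. Pecam1- and Cdh5-led cells lay beside pericyte-like cells more often than class shares give, with a log2 ratio of 1.43 ± 0.27 (SD, n = 3), and beside fibroblast-like cells at 0.71 ± 0.19. Fibroblast-like cells lay beside each other at 1.502 ± 0.31. Epithelial-like cells had fewer fibroblast-like neighbours (log2 ratio -0.77 ± 0.16) and fewer Pecam1- and Cdh5-led neighbours (-0.55 ± 0.06). The median epithelial-like cell was 45.3 ± 8.2 µm from a Pecam1- and Cdh5-led cell, 32.8 ± 7.0 µm from a fibroblast-like cell and 39.9 ± 15.3 µm from a myeloid-like cell. At clustering resolution 2 the epithelial-like share was 77.8% and the unnamed share 11.1%, but these names cover different clusters there. A cluster led by Il17b and Mgp, which are also among the top genes of the unnamed cluster at resolution 1, was named epithelial-like.

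Sox9, a progenitor and ductal transcription factor, had the highest mean level over the 3 tumours in epithelial-like cells, at 50.7 ± 3.4 per 1000 panel transcripts (SD, n = 3). The ranking is by that mean and not by each tumour. Gata3, the luminal fate regulator, stood at 41.0 ± 13.3 and the matrix glycoprotein gene Thbs1 at 38.0 ± 20.7. Pmepa1, Wwc1, Tgfb3, Jun, Lrp5 and Flna were among those that followed, between 36.3 ± 6.6 and 23.1 ± 3.5. Fn1, encoding fibronectin, varied most between tumours, at 3.51, 1.46 and 9.75 per 1000 (coefficient of variation 88.1%). Krt17 (78.7%), Axin2 (77.8%), the Notch ligand gene Dll1 (74.4%) and Mx1 (73.7%) came next, of which Axin2 and Mx1 were not above background in every tumour.

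At the margin, stromal classes took a larger share of the cells than in the interior. Fibroblast-like cells rose from 4.71% ± 1.31 to 19.99% ± 6.32 (SD, n = 3; log2 fold change 2.07 ± 0.44 SE, edgeR adjusted p = 0.0240). Pericyte-like cells rose from 0.777% ± 0.105 to 1.45% ± 0.14 (0.90 ± 0.06, adjusted p = 0.00563). The Pecam1- and Cdh5-led cluster rose by 0.70 ± 0.07 and myeloid-like cells by 0.70 ± 0.08 (both adjusted p = 0.00616). Epithelial-like cells fell from 89.5% ± 3.4 to 70.3% ± 2.2 (log2 fold change -0.35 ± 0.07, adjusted p = 0.0223). Each of these 5 classes moved the same way in 3 of 3 tumours, while unnamed cells gave 0.47 ± 1.12 (adjusted p = 0.700). Without tumour 2, 0 classes passed in edgeR, with 4 at an unadjusted p under 0.05 and the lowest adjusted p at 0.0569. Without tumour 1, 3 passed, and without the tumour as a block 3 passed, the myeloid-like class then at adjusted p = 0.421. At clustering resolution 2 the fall of epithelial-like cells did not pass (edgeR adjusted p = 0.0529), and myeloid-like cells gave 1.18. The myeloid-like class there included a cluster led by Cd163, Ccl8 and Folr2, so it does not cover the same cells.

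**Figure D1:**
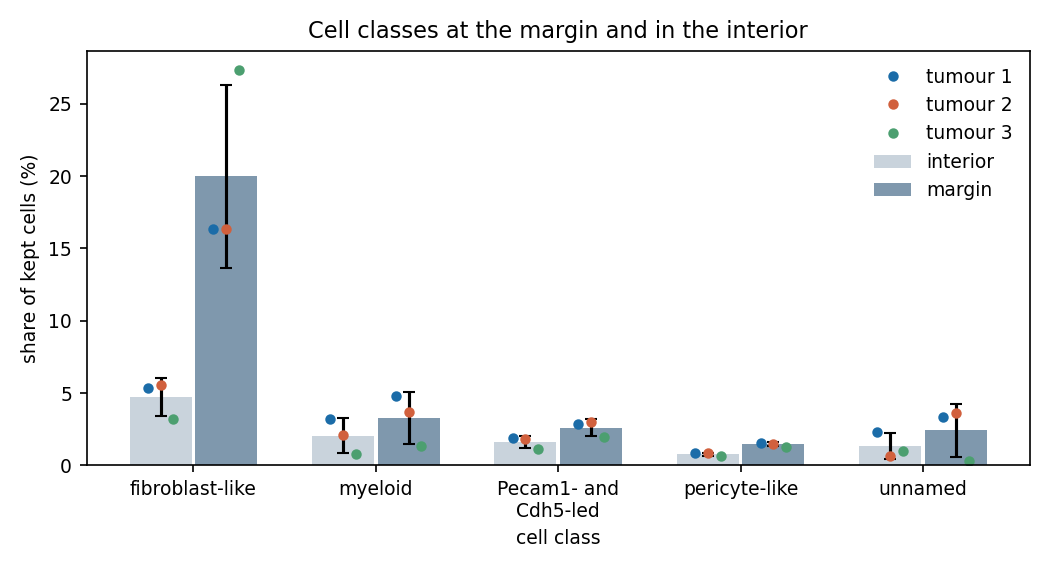
Share of kept cells in each class (%) at the margin and in the interior, for all classes but the epithelial-like one, with points for the 3 tumours, bars for the mean and error bars for the SD. Fibroblast-like cells stand at 19.99% at the margin and 4.71% in the interior.

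Within epithelial-like cells, 1 of 258 genes differed between margin and interior. Cd163, a macrophage scavenger receptor gene, was higher at the margin (0.221 ± 0.045 against 0.0984 ± 0.0156 per 1000, log2 fold change 0.90 ± 0.10 SE, adjusted p = 0.0258, n = 3). It was not above the blank background and stood at 1.15 per 1000 in fibroblast-like cells, whose share rose at the margin, against 0.110 in all epithelial-like cells, with the highest blank of fibroblast-like cells at 1.48. Fibroblast-like cells included the smaller cluster led by Clec3b and Cd163, which may hold macrophages. Cd163 is also on the macrophage list, so cells without marker transcripts could not test it. Among basal list members, which mark myoepithelial-type cells, Krt14 gave 1.31 ± 0.47 (adjusted p = 0.138) and Krt5 gave 0.69 ± 0.31 (adjusted p = 0.174). The matrix gene Tnc gave 0.66 ± 0.19 (adjusted p = 0.0995), Sox9 -0.56 ± 0.08 (adjusted p = 0.0737), the class I antigen gene H2-K1 -0.70 ± 0.18 and Nfkb1 -0.56 ± 0.12 (both adjusted p = 0.0814). Cells of basal keratin clusters made up 12.0% ± 3.8 of the margin and 4.75% ± 1.65 of the interior.

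No list was called by camera at the margin, and 0 members of any list passed over all genes in edgeR. Adjusted over the list alone, 2 of 9 epithelial-mesenchymal transition factors were higher and 1 lower, 1 of 7 stem or progenitor genes was higher and 1 lower, and Gata3 alone on the luminal list was lower. One member each was lower of the 15 inflammatory, 6 stress and 4 growth factor receptor genes. The luminal list has 1 member, so adjusting over it alone changes nothing. The median log2 fold change was -0.27 over the 132 genes above background and 0.17 over the other 126. Gata3 (-0.29) and the medians of the stress (-0.31) and receptor (-0.30) lists lie near the former. Such falls are not set apart from that shift. In a separate fit the 27 blanks had a median of 0.22. The sums held 1901668 to 3226484 transcripts at the margin and 41162818 to 59316610 in the interior, with 0.636% ± 0.049 and 0.451% ± 0.018 blanks. Scaling by library size alone moved the median gene from 0.01 to 0.27 and called 78 genes higher and 1 lower, and DESeq2 called 49 and 59. Leaving out tumour 1 gave 25 higher and 10 lower, leaving out tumour 2 gave 0 in edgeR (45 at an unadjusted p under 0.05, against 79 with all 3 tumours), and leaving out tumour 3 gave 1 and 1.

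Both measured proliferation genes rose in epithelial-like cells near the Pecam1- and Cdh5-led cluster. Mki67, a marker of cycling cells, rose from 4.25 ± 2.01 to 7.78 ± 3.01 per 1000 (log2 fold change 0.86 ± 0.10 SE, adjusted p = 0.0162, n = 3), and Top2a, the mitotic topoisomerase gene, rose by 0.63 ± 0.11 (adjusted p = 0.0486). Both measured members of the proliferation list passed, also adjusted over the list alone. Pecam1- and Cdh5-led cells lay beside fibroblast-like cells more often than class shares give (log2 ratio 0.71), and Mki67 also passed as higher near fibroblast-like cells. The rise was not tested for each neighbour apart from the other. Krt5, a basal keratin, rose by 1.03 ± 0.14 (adjusted p = 0.0299), and cells of basal keratin clusters made up 8.01% ± 1.62 near and 3.43% ± 0.74 far. Leaving out epithelial-like clusters with more markers of another class, one of them led by Top2a and Mki67 themselves, gave 0.54 for Mki67 (adjusted p = 0.0904) and 0.24 for Top2a (adjusted p = 0.297), which then did not pass. Cd14, a lipopolysaccharide co-receptor gene, fell by 0.58 ± 0.10 (adjusted p = 0.0486).

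In all, 13 of 255 genes were higher and 2 lower, 9 and 1 of them above background, each with 1 sign in 3 of 3 tumours. Of the 13, 10 were also higher in the Pecam1- and Cdh5-led cluster than in epithelial-like cells, which left Mki67, Top2a and Krt5. The 10 include the matrix genes Sparc (1.12 ± 0.11) and Col1a1 (1.11 ± 0.11), the pericyte gene Pdgfrb (0.94 ± 0.11), Mgp (0.86), Pi16 (0.83), Foxc2 (0.83), Thy1 (0.70), Snai2 (0.64), Mmp2 (0.49) and Rgs5 (0.45), with Foxc2, Thy1, Snai2 and Mmp2 not above background in every tumour. Pdcd1, not above background, was the other lower gene (-0.39). In a separate edgeR fit with the 27 blanks added to the genes, 6 blanks were called lower and 0 higher, with the lowest at -0.40. A blank with an unadjusted p of 0.0136 passed there (edgeR adjusted p = 0.0478), so that count is not at the threshold of the main fit.

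Of 5 basal list members 1 passed, and adjusted over the list alone 3 were higher and 1 lower. Trp63, the basal fate regulator, gave 0.66 ± 0.15 (adjusted p = 0.0680). Of 9 transition factors 2 passed as higher (3 adjusted over the list alone), and of 16 mesenchymal genes 1 (1 adjusted over the list alone). None of 6 stress genes passed over all genes and 5 were lower adjusted over the list alone. Camera called that list lower (adjusted p = 0.0137), but not with its correlation estimated (adjusted p = 0.638 with an estimated correlation). None of 11 interferon genes passed over all genes, 6 were lower adjusted over the list alone, and camera gave adjusted p = 0.0355 (adjusted p = 0.638 with an estimated correlation). The sums held 3683408 to 19297661 transcripts. Without tumour 2, 0 genes passed in edgeR (43 at an unadjusted p under 0.05), without tumour 1 23 were higher and 11 lower, and without tumour 3 30 and 10. Library size alone gave 33 and 11, cell volume 34 and 0 with the median gene at 0.15, DESeq2 43 and 62, and no block 2 and 0. Without clusters with more markers of another class 2 were higher and 0 lower, and in cells with no marker transcript 8 and 0. The balance turned to mostly lower with at least 40 transcripts per cell (30 higher and 43 lower), near 15 µm and far 50 µm (38 and 53) and 500 µm or more from the edge (34 and 48).

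In epithelial-like cells near fibroblast-like cells, 4 of 5 basal genes rose, and 4 of 6 stress and 5 of 11 interferon genes fell. Krt5 rose from 2.26 ± 2.03 to 8.35 ± 2.62 per 1000 (log2 fold change 2.10 ± 0.36 SE, adjusted p = 0.0119, n = 3). Trp63 rose by 1.19 ± 0.17 (adjusted p = 0.00994), Krt15, not above background in every tumour, by 1.37 ± 0.25 and Krt14 by 1.01 ± 0.26. Atf3, an early stress transcription factor, fell from 3.32 ± 1.35 to 1.10 ± 0.18 (-1.63 ± 0.19, adjusted p = 0.00707), and Klf4, an epithelial differentiation factor, fell by 1.43 ± 0.17. Mx1, an interferon-induced antiviral gene not above background in every tumour, fell by 1.28 ± 0.36 (adjusted p = 0.0418).

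Over 251 genes, 27 were higher and 42 lower, 14 and 19 of them above background, each with 1 sign in 3 of 3 tumours. Of 5 basal genes 4 rose, 4 also adjusted over the list alone, while Krt17 gave -0.68 ± 0.37. Camera called the basal list higher at adjusted p = 0.0278 (adjusted p = 0.487 with an estimated correlation). Of 6 stress genes 4 fell, Atf3, Fosb (-1.09), Fos (-0.48) and Jun (-0.42), 4 also adjusted over the list alone. Camera gave adjusted p = 0.0278 for it (adjusted p = 0.487 with an estimated correlation). Of 11 interferon genes 5 fell, Mx1, Ifit1 (-0.94), Ifit3 (-0.77), Cxcl10 (-0.58) and Cd274 (-0.47), and 7 adjusted over the list alone. None of these 5 was above background in every tumour. Camera gave adjusted p = 0.0278 here too (adjusted p = 0.487 with an estimated correlation). Isg15, above background, gave -0.65 ± 0.20 (adjusted p = 0.0532).

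Sparc, a matrix protein gene, rose by 1.82 ± 0.15 (adjusted p = 0.00389), and the laminin gene Lama3, not above background in every tumour, by 1.29 ± 0.26. Of 16 mesenchymal genes 4 rose, these among them, 4 adjusted over the list alone. Of 9 transition factors 3 rose, Snai2 (1.05), Foxc2 (0.71) and Zeb2 (0.50), and Prrx1 fell (-0.60), none of these above background, with 4 and 1 adjusted over the list alone. Mki67 rose by 0.63 ± 0.16 as 1 of 2 proliferation genes (2 adjusted over the list alone). Klf4, Cd44 (-0.50) and Lgr5 (-0.44, not above background) fell of 7 stem or progenitor genes, and Cldn4, a tight junction gene, fell by 0.75 ± 0.15 as 1 of 4 adhesion genes. Of 15 inflammatory genes 1 rose, Il33 (0.84), and 2 fell, Il1a (-0.34) among them, none above background, with 1 and 2 adjusted over the list alone. The Wnt inhibitor gene Wif1 rose by 1.42 ± 0.28 and the Notch ligand gene Jag2 by 1.34 ± 0.26. Arg1 fell by 1.08 ± 0.19, Lama5 by 0.88, Anxa1 by 0.84, and Thbs1 from 54.6 ± 37.1 to 28.9 ± 12.7 per 1000 (-0.88 ± 0.18).

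Of the 27 higher genes, 17, Sparc, Pdgfrb, Snai2 and Jag2 among them, were also higher in fibroblast-like cells, while Krt5, Krt14, Krt15, Trp63, Lama3, Wif1 and Mki67 were not. Without the basal keratin clusters Krt14 gave 0.43 (adjusted p = 0.549), while Krt5 gave 1.43 and Trp63 1.03, both still past the threshold. Cells of basal keratin clusters made up 8.95% ± 0.36 near and 1.27% ± 1.003 far. In a separate fit with the 27 blanks added to the genes, 8 blanks were called lower and 0 higher, down to -0.50. Small falls of genes near background lie within the range of the blanks. The sums held 1053835 to 29897882 transcripts. Without tumour 1, 0 genes passed in edgeR (61 at an unadjusted p under 0.05), without tumour 2 20 were higher and 12 lower, and without tumour 3 22 and 10. Library size alone turned the balance to 38 higher and 25 lower. Cell volume gave 26 and 52 with the median gene at -0.16, DESeq2 gave 58 and 74, and no block 3 and 0. The balance also turned to mostly higher near 15 µm and far 50 µm (37 and 26) and without marker transcripts (11 and 7). Cells 500 µm or more from the edge gave 26 and 22, and added unnamed cells 9 and 4. Leaving out clusters with more markers of another class gave 20 and 9. At clustering resolution 2, 0 passed in edgeR (59 at an unadjusted p under 0.05). All 69 genes kept their sign in each alternative run on all genes.

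**Figure D2:**
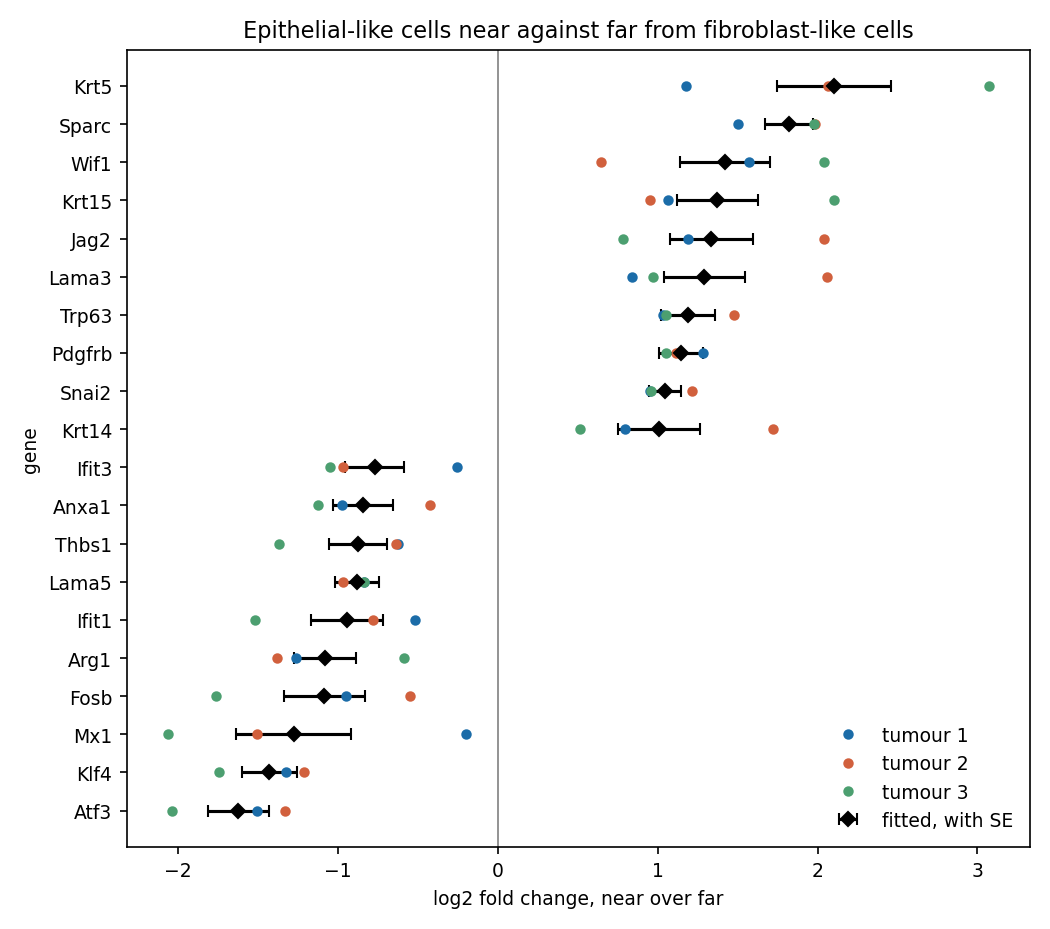
Log2 fold change of genes in epithelial-like cells near against far from fibroblast-like cells, with points for the 3 tumours and diamonds for the fitted value with its SE. Krt5 (2.10) and Sparc (1.82) stand highest and Atf3 (-1.63) lowest, and all 3 tumours lie on 1 side of 0 for each of them.

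In epithelial-like cells near myeloid-like cells, 4 of 11 interferon genes fell. Isg15, a ubiquitin-like interferon effector gene, fell from 3.73 ± 1.96 to 1.45 ± 0.78 per 1000 (log2 fold change -1.39 ± 0.17 SE, adjusted p = 0.0193, n = 3). Irf7, a regulator of type I interferon, fell from 12.4 ± 6.3 to 6.67 ± 2.72 (-0.87 ± 0.15, adjusted p = 0.0422). Ifit1 (-1.40 ± 0.25) and Ifit3 (-1.34 ± 0.24), which encode interferon-induced RNA-binding proteins, passed too and were not above background in every tumour. Cells of the clusters led by interferon genes made up 1.01% near and 3.10% far in tumour 1, 4.27% and 12.1% in tumour 2, and 4.05% and 21.6% in tumour 3. Within 300 µm tiles holding both arms the 4 genes kept a median share of 0.264, 0.254 and 0.218 of their log2 ratio in tumours 1, 2 and 3. Klf4 fell by 0.96 ± 0.17, and Aldh1a3, an aldehyde dehydrogenase gene not above background, by 0.86 ± 0.17.

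These were the 6 lower of 245 genes. Sparc (0.63 ± 0.12), Pi16 (0.53 ± 0.10) and the fibroblast receptor gene Pdgfra (0.72 ± 0.14) were the 3 higher ones, all also higher in the myeloid-like cluster and in fibroblast-like cells, where Sparc stood at 71.5 against 13.3 per 1000 in epithelial-like cells, Pi16 at 4.17 against 0.310 and Pdgfra at 2.76 against 0.582. All 9 had 1 sign in 3 of 3 tumours. Of 11 interferon genes 4 fell, and 7 adjusted over the list alone. Camera called the list lower at adjusted p = 0.000436, a call lost with its correlation estimated (adjusted p = 0.737 with an estimated correlation). None of 6 stress genes passed over all genes and 1 was lower adjusted over the list alone, with camera at adjusted p = 0.00718 (adjusted p = 0.737 with an estimated correlation). Of 7 stem or progenitor genes 2 fell. Mx1 gave -1.95 ± 0.47 (adjusted p = 0.0749) and Krt17 -1.67 ± 0.41 (adjusted p = 0.0823). In a separate edgeR fit with the 27 blanks added to the genes, 0 blanks were called.

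The sums held 607264 to 29366165 transcripts, the fewest in the far arm. Scaling by cell volume moved the median gene to 0.20 and called 4 genes higher and 0 lower, DESeq2 called 23 and 34, and without the block edgeR called 0 (18 at an unadjusted p under 0.05). Without tumour 1, 0 were higher and 2 lower, without tumour 2 6 and 13, and without tumour 3 8 and 11. In cells with no marker transcript, 0 passed in edgeR (41 at an unadjusted p under 0.05), with the sign of all 9 genes unchanged. A minimum of 40 transcripts per cell gave 0 (59 at an unadjusted p under 0.05). Leaving out clusters with more markers of another class gave 0 (47), and clustering resolution 2 gave 0 higher and 1 lower.

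**Figure D3:**
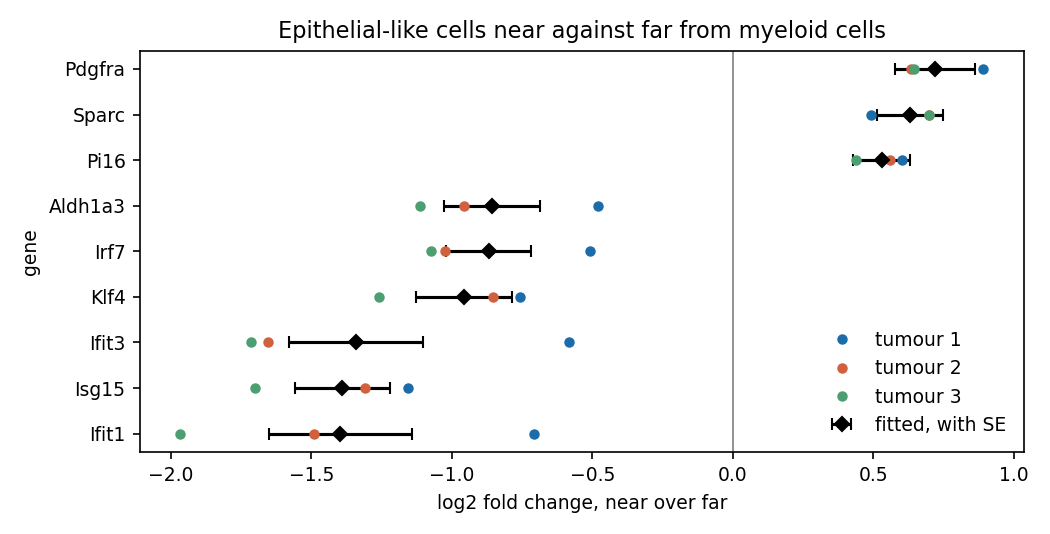
Log2 fold change of genes in epithelial-like cells near against far from myeloid-like cells, with points for the 3 tumours and diamonds for the fitted value with its SE. Isg15 stands at -1.39 and Irf7 at -0.87, with all 3 tumours below 0.

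Within the epithelial-like cells, 114 of 258 genes were spatially structured in all 3 tumours, 104 of the 132 above background and 10 of the other 126. Wif1 had the highest mean Moran's I at 0.894 ± 0.061 (SD, n = 3), followed by the matrix gene Chad (0.833 ± 0.049), H2-K1 (0.818 ± 0.042), Sox9 (0.814 ± 0.040) and Arg1 (0.813 ± 0.076). Tead2, Timp2, Irf7, Wnt5b, Nfkb1, Tgfb3, Ltbp2, Jag1, Notch2 and Tnfrsf1b completed the top 15, down to 0.736 ± 0.135. The highest blank reached 0.348, 0.301 and 0.437 in tumours 1, 2 and 3, and the highest shuffled gene 0.032, 0.046 and 0.025. In simulated bins with all gradients in 1 direction, 68 of 218 unchanged genes counted, with an I of up to 0.378. Some of the 114 genes may therefore be carried by others, and which ones was not tested.

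All 5 basal, 6 stress and 4 growth factor receptor genes counted, with Krt14 (0.707 ± 0.156), Atf3 (0.620) and Jag1 (0.744) highest. Of 11 interferon genes 8 counted, of 16 mesenchymal genes 10 (Lamb3 highest at 0.715), of 7 stem or progenitor genes 5 (Id2, 0.675), of 15 inflammatory genes 6 and of 4 adhesion genes 3 (Grhl2, 0.704). Of 9 transition factors 2 counted, of 3 lipid genes 1 (Cpt1a, 0.699) and of 2 proliferation genes 1 (Mki67, 0.566 ± 0.120). Gata3 (0.719) and the milk protein gene Wap (0.636, not above background) were the sole members of the luminal and milk lists. Above background were 2 of the 9 transition factors, 1 of the 3 lipid, 10 of the 16 mesenchymal and 7 of the 15 inflammatory genes. Of the interferon genes 5 of 11 were above it, of the stress genes 6 of 6 and of the receptor genes 4 of 4. Counts per list therefore follow detection in part and do not rank the lists. With bins of 50 µm 65 genes counted, all of them among the 114.

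**Figure D4:**
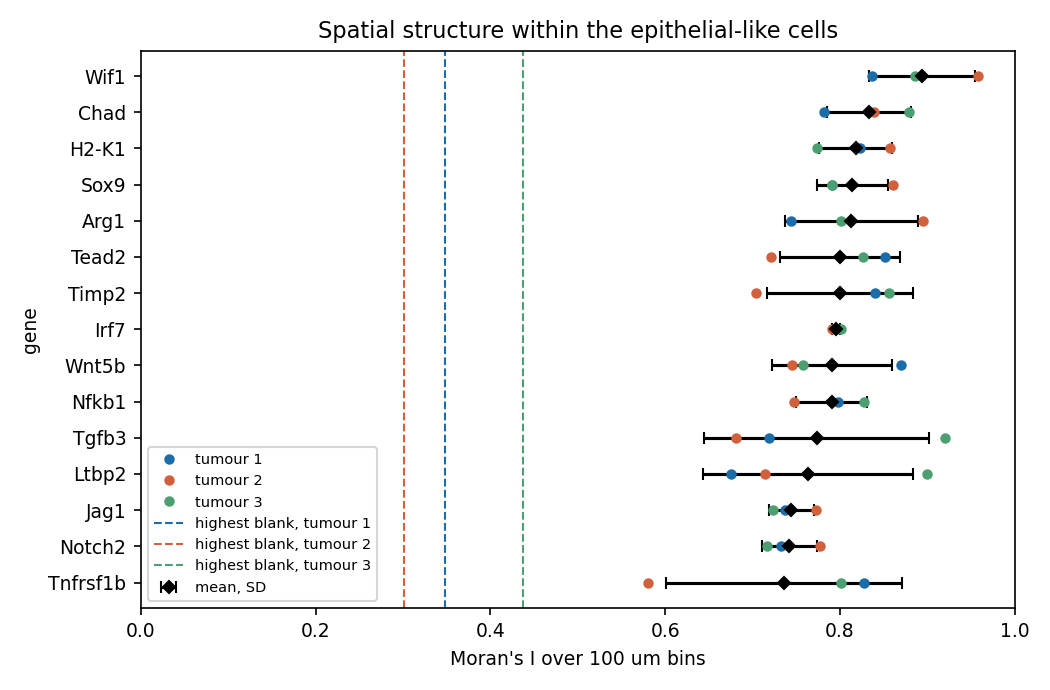
Moran's I over bins of 100 µm for the 15 genes with the highest mean, with points for the 3 tumours, mean and SD, and dashed lines at the highest blank of each tumour. Wif1 stands highest at 0.894, and all points lie above the blank of their tumour.

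Across bins, the score of the transition factors and that of the inflammatory genes correlated positively in each tumour, at Pearson r of 0.0856, 0.0945 and 0.114 (mean 0.0981 ± 0.0147 SD over tumours). The mean r was 0.0220 in cells without marker transcripts, 0.0407 at clustering resolution 2, 0.0440 in bins of 50 µm and 0.183 in bins of 200 µm. Only 2 of the 9 transition factors were above background, and no r between blanks was computed. Bins are not independent replicates, so no p was computed. The other 3 computable pairs had signs that differed between tumours and did not hold. Mesenchymal with adhesion genes gave a mean r of -0.00599 ± 0.0325, mesenchymal with inflammatory genes 0.0142 ± 0.0963, and proliferation with mesenchymal genes -0.0434 ± 0.101.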

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

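Tests on genes above the highest blank alone were chosen after the results were seen. So were those without basal keratin clusters and without clusters with more markers of another class. Of the single genes and class shares named, 1684 results kept their direction and side of the threshold, 175 passed newly, 509 no longer passed and 18 reversed. The 1684 include results that passed in neither fit and those without the gene filter. Near fibroblast-like cells 439 kept direction and side, 6 passed newly, 332 no longer passed and 5 reversed. Causes of the changes were not tested. Counts of genes called follow for the margin, the Pecam1- and Cdh5-led, the fibroblast-like and the myeloid-like neighbour in that order, from 1, 15, 69 and 9. DESeq2 called 108, 105, 132 and 57, and edgeR without the tumour block 0, 2, 3 and 0. Library size alone called 79 and 44 in the first pair, and cell volume 3, 34 and, for the last, 4. Cells with no marker transcript gave 0, 8, 18 and 0. Resolution 2 gave 9, 9, 0 and 1. Without basal keratin clusters 5, 7, 43 and 15 passed, and without clusters with more markers of another class 0, 2, 29 and 0. Adding unnamed cells gave 8, 13 and 1 for the neighbours. A minimum of 40 transcripts gave 73 for the Pecam1- and Cdh5-led and 0 for the myeloid-like neighbour, and a minimum of 10 gave 44 for the fibroblast-like one. Near 15 µm and far 50 µm gave 91 and 20 for the first and last neighbour, near 40 µm and far 120 µm gave 2 for the fibroblast-like one, and cells 500 µm or more from the edge gave 82 and 5. A margin of 100 µm with an interior of 300 µm gave 5, and 300 µm with 1000 µm gave 0. On genes above the highest blank, 0 passed at the margin and 22 near fibroblast-like cells. At an unadjusted p under 0.05 in edgeR, the margin and the myeloid-like neighbour had 19 and 18 genes without the block. They had 25 and 41 without marker transcripts, and 80 and 47 without clusters with more markers of another class. The wide margin had 50, genes above the blank 26, resolution 2 near fibroblast-like cells 59 and 40 transcripts near myeloid-like cells 59. Leaving out each tumour gave 0 (tumour 2) to 35 (tumour 1) at the margin, 0 (tumour 2) to 40 (tumour 3), 0 (tumour 1) to 32 (tumour 2), and 2 (tumour 1) to 19 (tumour 2). Class shares passed in 0 (tumour 2) to 5 classes, 3 without the block and 4 at resolution 2. Reversed at the margin were Grhl2 (0.026), Cpt1a (0.021) and Fabp5 (0.11) by library size, and Fabp5 (0.34) and Cxcl9 (-0.17) without marker transcripts. Near Pecam1- and Cdh5-led cells Cpt1a gave -0.014 without clusters with more markers of another class. Notch2 gave 0.095 by cell volume and 0.032 at 40 and 120 µm there, and Jag1 -0.076 to 0.36 over left-out tumours. Near fibroblast-like cells, resolution 2 gave Cpt1a 0.038 and Fabp5 0.071, and Fabp5 ran from -0.22 to 0.025 over left-out tumours. Notch1 gave 0.061 there without marker transcripts and 0.043 without clusters with more markers of another class. Near myeloid-like cells Lgr5 gave 0.030 by cell volume. Cpt1a gave -0.060 there without clusters with more markers of another class and -0.074 to 0.31 over left-out tumours. The share of unnamed cells, also reversed at the margin, ran from -0.56 to 1.52 over left-out tumours. Bins of 50 µm counted 65 structured genes, and all other settings 98 to 124. Transition factors with inflammatory genes gave r of 0.0407 at resolution 2, 0.183 and 0.0440 in bins of 200 and 50 µm, 0.0220 without marker transcripts and 0.122 without basal keratin clusters. Mesenchymal with adhesion genes gave -0.109 at resolution 2, 0.0460 in bins of 200 µm and 0.0270 without basal keratin clusters. Resolution 2 gave 77.8% epithelial-like and 11.1% unnamed cells, with unnamed cells beside each other at 0.83. A cluster led by Il17b and Mgp was named epithelial-like there, and other clusters were unnamed. The 0.83 is therefore not for the same cells as the main value. Pairs within 50 µm gave 0.76 for Pecam1- and Cdh5-led with pericyte-like cells, 0.40 with fibroblast-like, -0.25 with epithelial-like, -0.50 for epithelial-like with fibroblast-like, and 1.13 for fibroblast-like cells with each other. Camera made 7 list calls at the preset correlation and 0 with an estimated one. The gene filter removed nothing, so omitting it tested nothing, and near 40 µm with far 120 µm gave no value for myeloid-like cells because 1 arm held under 100 cells. Of 258 genes, 126 were not above the highest blank in at least 1 tumour.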

Other observations

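Tests of Mki67 and Top2a levels in the neighbour cluster and of the basal list members were chosen after the result was seen, as were the cells and genes of the first 2 paragraphs. Cells of the unnamed cluster lay beside each other at a log2 ratio of 4.17 ± 0.24 (SD, n = 3) and took 2.82%, 1.18% and 0.856% of cells in tumours 1, 2 and 3. Il17b, a cytokine gene, was 33.6-fold higher there than in epithelial-like cells (13.3 ± 5.2 against 0.397 per 1000). The contractile genes Acta2 (23.7-fold, 8.24 ± 2.80) and Myl9 (13.0-fold, 9.49 ± 1.03) were higher too. Mgp stood at 25.9 ± 14.7 (15.8-fold), the basement membrane gene Col4a1 at 139 ± 77 (10.004-fold) and Mmp2, on the fibroblast list, at 3.40 ± 0.51 (8.25-fold). The highest blank in this cluster stood at 0.641. Ecrg4, Ccnd2, Tagln and Sox11 had higher means as well but spread widely between tumours, Sox11 at 1.91 ± 1.91.

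Epithelial-like clusters were unevenly spread over tumours. A cluster led by the Notch ligand gene Dll1 took 8.54%, 29.6% and 9.65% of cells in tumours 1, 2 and 3. One led by Wnt7b and Jag1 took 24.8%, 2.27% and 14.15%, and one led by Wif1 and Chad took 4.94%, 1.58% and 14.97%. A cluster led by Krt17, Fosb and Fn1 took 1.89%, 1.63% and 9.42%. In fibroblast-like cells the T cell receptor gene Cd3g stood at 1.70 ± 0.74 per 1000, near the highest blank in that class (1.48), and Ctla4 at 0.699, below it. Neither gene was above background in any tumour.

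Genes higher near fibroblast-like cells were weighed against 3 technical sources. In cells without a fibroblast marker transcript the 27 genes kept a median share of the log2 fold change of at least 0.727 in each tumour. The 17 genes higher in fibroblast-like cells kept 0.593 to 0.712, and the 10 others 0.924 to 1.04. A cell without a marker transcript can still hold other transcripts of a neighbour, so for the 17 genes that source stays open. For the 10 others, not higher in fibroblast-like cells, the values argue against it as the whole source. Without basal keratin clusters the 27 genes kept at least 0.908, and the 4 basal members at least 0.650. Single basal members kept from -0.807 to 1.02 and Krt14 no longer passed. As a median over the 27 genes or the 4 basal members, a larger share of cells with those labels accounts for part at most. For a single member with a negative share kept, it can account for the whole change in that tumour. Basal cells under other labels stayed in, as did the cluster led by Krt17 (14.9-fold), Fosb and Fn1. A larger share of basal cells at large was therefore not tested. Within 300 µm tiles holding both arms the 27 genes kept at least 0.592, against larger regions as the whole source. No biological explanation was tested.

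Lower interferon genes near myeloid-like cells cannot be told apart from regions of the section, since the 4 genes kept a share of 0.218 within 300 µm tiles in the lowest tumour and 0.264 and 0.254 in the others, around the bound of 0.25. Cells of the clusters led by interferon genes made up 1.01% near and 3.10% far in tumour 1, 4.27% and 12.1% in tumour 2, and 4.05% and 21.6% in tumour 3. Without them the genes kept 0.504, 0.387 and 0.302, of which 1 lies just above the upper bound of 0.5 and the others between it and 0.25, so this source cannot be told apart either. Those clusters were taken for high levels of interferon genes, the 4 tested genes among them. A smaller change can therefore follow from the removal alone. No biological explanation was tested.

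Mki67 and Top2a near the Pecam1- and Cdh5-led cluster kept a share of at least 0.663 within 300 µm tiles in each tumour, against larger regions as the whole source. Their level in that cluster was at most 0.455 of the level in near cells, which argues against its transcripts as the source. Without epithelial-like clusters with more markers of another class, the log2 fold changes were 0.54 and 0.24 and neither passed. That setting takes out a cluster led by Top2a and Mki67 themselves. A smaller change of these genes can follow from the removal alone, so the setting does not test their source. No biological explanation was tested.

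The 10 splits of the 6 sums are too few for a share under 0.05 in each comparison. Near Pecam1- and Cdh5-led cells 15 genes passed and at most 0 in any other split (edgeR; 1 of 10 splits as large), near fibroblast-like cells 69 against 0 (1 of 10), and near myeloid-like cells 9 against 0 (1 of 10). At the margin 3 of 10 splits gave as many as the real 1, with 6 in the highest, which parted 1 of the 3 pairs. The other splits that parted all 3 pairs gave 0 there.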
